A study of Mus musculus with 16 samples.

How the data were processed

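RNA from the lungs of 16 female A/J mice, an inbred strain prone to lung tumours, was measured on 16 2-colour Agilent arrays. The 4 groups of 4 mice were Untreated, NNK (a tobacco-specific nitrosamine, given as 1 intraperitoneal injection), SECY (selenocystine, a selenium-containing amino acid, in the diet) and NNK+SECY (both). Per the labels, NNK was given as 0.2 mL of saline at 10 uM, selenocystine was fed at 15 ppm for 10 days on a basal diet holding 0.35 ppm selenium, and it was started 3 days after NNK in the NNK+SECY group. NNK-injected mice were killed 13 days after the injection. The labels call the 4 mice of a group biological replicates and put every RNA above 9 on a scale of RNA quality. On every array the lung sample was labelled with Cy5 (red) and the reference with Cy3 (green). The reference was an equal mix of the RNA of the 4 untreated mice, and no dyes were swapped. A dye effect of a gene that is the same on every array therefore drops out of the comparisons. One that differs between slides or scan days would not.

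The authors scanned the arrays and extracted the spots with Feature Extraction 8.1.1.1, per the file headers. The deposited files hold spot and background intensity in both colours on a linear scale. They also hold processed signals as intensity and a log10 ratio of red over green, made with spatial detrending, no global background correction and a linear and lowess dye normalization, per the file headers. A deposited value table holds log2 ratios of the same arrays. The authors' log2 values equal the file's log10 ratio put on the log2 scale within 0.005 on every array, so red over green is its direction, and the median of every column is 0. Each array has 43790 features, of which 41534 are not controls, and these are 41174 distinct probes. Of these probes, 22072 were named through their RefSeq accession, 6280 through their symbol and 4226 through a synonym in a gene table of assembly GRCm38.p6, and 8596 kept the name in the file. No positions are given, because the build of the array's own annotation is not given in the sources used here.

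Mean spot signals were corrected with limma's normexp and an offset of 50 and normalized within each array by loess, with control spots and spots flagged as outliers at weight 0 (R 4.3.3 with limma 3.58.1 and version 1.17.8 of data.table). Replicate spots of a probe were averaged. Each gene was represented by its probe with the highest mean intensity over the 16 arrays, and it was tested where that probe was well above background in Cy5 on all 4 arrays of at least 1 group. This left 21248 of 27703 gene names, of which 8333 had more than 1 probe. Flags left 591 of the tested genes without a value on at least 1 array, and 11 without a value in a group. Signal per dye was taken after loess and Aquantile scaling.

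A limma model with a mean for each group was fitted over all 16 arrays (lmFit and eBayes), with p-values adjusted by Benjamini-Hochberg over the genes tested and a threshold of 0.05. The comparisons were the 5 pairs NNK vs Untreated, SECY vs Untreated, NNK+SECY vs Untreated, NNK+SECY vs NNK and NNK+SECY vs SECY, and the interaction, which is the NNK effect under selenocystine minus the NNK effect without it. Fold changes are given as log2 with the standard error (SE) of the model and n = 4 arrays per group. The groups, the model, the lists and the alternatives were fixed before the data were examined. The genes named are, per comparison, the called genes with the 12 largest changes each way whose groups of 4 arrays do not overlap and whose name is not that of a clone or an accession (for the interaction, 6 each way with no rule on overlap), up to 4 members with the smallest p of each list that passed or holds a called gene, and 12 genes named whatever their values (Gpx1, Gpx3, Txnrd1, Selenow, Selenop, Cyp2a5, Cyp2f2, Cdkn1a, Mgmt, Per2, Arntl and Dbp). Where fewer than 5 genes pass, the 8 named genes with the smallest p are given as values. Not every gene this rule takes is printed.

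Gene lists were tested with camera at its preset correlation of 0.01, adjusted over the 38 lists of a comparison, and again with a correlation estimated from the residuals. For these tests a missing value was set to the mean of its group. The lists with their measured members were NRF2 targets and glutathione enzymes (36), selenoproteins (22), p53 targets (31), DNA repair (36), xenobiotic phase I enzymes (32), circadian clock (18), proliferation (34), type I interferon response (25), inflammatory cytokines and acute phase (23), cholesterol synthesis (24), fatty acid synthesis and oxidation (27), ER stress and amino acid response (28), heat shock (19), immediate early genes (23), glucocorticoid response and metallothioneins (19), extracellular matrix (27), RAS-MAPK output (18) and mitochondrial respiratory chain (34). Lists of cell type markers covered alveolar type 2 (16), alveolar type 1 (13), club (14), ciliated (22), endothelial (18), fibroblast and smooth muscle (20), alveolar macrophage (19), neutrophil and granulocyte (13), T and NK (26), B and plasma (19) and mast cells (8), antigen presentation class II (15), erythroid (12) and platelet and megakaryocyte (12) cells, adipose tissue (18), cardiac muscle (20), skeletal muscle (13), mesothelium (9), thymus and immature T cells (9) and tracheal and esophageal epithelium (8).

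The steps were tested on simulated data built for SECY vs Untreated with 21248 genes, 50 of them changed at each fold. The model called 29 of 50 genes changed 1.25-fold, 49 of 50 changed 1.5-fold, 46 of 50 changed 2-fold and 50 of 50 changed 3-fold, with 8 unchanged genes called. At most 1 gene was called in any of 10 sets with no change. A list changed 1.25-fold was called and 0 other lists were. Genes and arrays were simulated independently, with no effect of slide or scan day, so these counts do not cover genes that move together.

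The 16 arrays lie on 8 slides of 2 arrays and were scanned on 2 days. Slides 1 to 4 each hold an Untreated and an NNK array, and slides 5 to 8 each hold a SECY and an NNK+SECY array. The NNK and NNK+SECY arrays were scanned on the same day, and the Untreated and SECY arrays on the other. The slide set therefore cannot be told apart from selenocystine, nor the scan day from NNK. The alternatives were other background corrections, dye normalizations and filters, the processed signals and the value table, flagged spots kept, the mean of all probes, the compared arrays alone, array weights, another moderation, blocks, a 1.5-fold threshold and leaving out each array. A restriction to genes whose reference signal differed by at most 0.5 (log2) between the group means, and another to the brighter genes, were added after the data were seen. The precision of every value is limited by the number of arrays, and the SE does not include the choice of processing.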

Results

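Lung transcripts were measured in 16 female A/J mice, 4 in each of the groups Untreated, NNK, SECY and NNK+SECY, each on 1 array against a pool of the untreated lungs. The median spot signal ranged from 71.2 to 105 in Cy5, which held the mouse's own RNA, and from 67.5 to 93.4 in Cy3, which held the pool. Between 66.3% and 79.3% of spots per array were well above background in Cy5. The share was 66.3% to 72.6% on slides 1 to 4, which hold Untreated and NNK, and 75.0% to 79.3% on slides 5 to 8, which hold SECY and NNK+SECY. The mean correlation of an array's gene values with those of the other arrays of its group ranged from 0.0389 for SECY 3 to 0.566 for NNK+SECY 2.

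The diet comparison asked which lung transcripts differed after 10 days of selenocystine. Large rises of SECY over Untreated (log2 fold change ± SE, n = 4 per group) were in enzymes of antioxidant defence and conjugation. Nqo1, a quinone reductase, rose by 1.43 ± 0.13, and Srxn1, which restores oxidised peroxiredoxins, rose by 1.34 ± 0.13. The glutathione S-transferases Gsta1, Gstm1 and Gstp1 rose by 0.95 ± 0.10, 0.88 ± 0.09 and 0.86 ± 0.08. The carboxylesterases Ces1g and Ces1f rose by 1.48 ± 0.08 and 0.92 ± 0.09, and Gbe1, the glycogen branching enzyme, rose by 0.82 ± 0.10. In each of these genes all 4 SECY arrays lay above every Untreated array, which the naming rule asks of the genes with the largest changes. All of them passed the limma threshold under each of their alternatives. Other probes of Srxn1 gave 0.47 to 0.61, and another probe of Ces1g gave 1.37.

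Of the 36 measured NRF2 targets and glutathione enzymes, 17 rose, 0 fell and 19 did not pass, and 26 rose when adjusted over the list alone (camera, median 0.41, adjusted p = 1.01e-55, and adjusted p = 4.63e-07 with an estimated correlation, given after the word estimated from here on). Among 22 selenoproteins 2 rose, namely Gpx2, a gastrointestinal-type glutathione peroxidase, by 1.08 ± 0.11 and Txnrd1, the cytosolic thioredoxin reductase, by 0.81 ± 0.09. The same 2 rose when adjusted over the list alone, and the list as a whole did not pass (adjusted p = 0.0906). The selenoprotein transcripts Gpx3 and Selenow had log2 fold changes of -0.04 ± 0.14 and -0.09 ± 0.07 and did not pass. Of 31 p53 targets 3 rose, 0 fell and 28 did not pass, and 7 rose when adjusted over the list alone (median 0.11, adjusted p = 4.12e-10, estimated 0.00162). They were Psrc1, a microtubule-associated protein, at 0.85 ± 0.14, the stress cytokine Gdf15 at 0.51 ± 0.07 and Ddit4l, an inhibitor of mTOR signalling, at 0.40 ± 0.07, of which Psrc1 passed under 32 and Ddit4l under 28 of 33 alternatives. Other probes of Psrc1 gave 0.038 to 0.31, and those of Ddit4l 0.16 to 0.40. Cdkn1a, the cell cycle inhibitor p21, was at 0.45 ± 0.22 and did not pass. Of 32 xenobiotic phase I enzymes 2 rose, Ces1g and Aldh1a1, a retinal dehydrogenase, at 0.73 ± 0.09, with 30 that did not pass and 6 that rose when adjusted over the list alone (median 0.11, adjusted p = 9.56e-07, estimated 0.0704). Aldh1a1 was also the sole called member of the 14 club cell markers, a list that did not pass (adjusted p = 0.0875).

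In 5 further lists no member passed. Alveolar macrophage markers were lower as a list (19 members, median -0.15, adjusted p = 0.00134, estimated 0.24), as were alveolar type 2 cell markers (16 members, median -0.14, adjusted p = 0.00328, estimated 0.144) and T and NK cell markers (26 members, median -0.072, adjusted p = 0.0461, estimated 0.79). Proliferation genes were higher as a list (34 members, median 0.041, adjusted p = 0.0346, estimated 0.79), as were DNA repair genes (36 members, median 0.029, adjusted p = 0.0346, estimated 0.24). Of 31 alternatives, T and NK cell markers passed under 19, DNA repair genes under 22 and proliferation genes under 24. Single genes also fell under selenocystine, among them Mamdc2 at -0.61 ± 0.09 and Igfbp3, a carrier of insulin-like growth factors, at -0.57 ± 0.08, of which another probe gave -0.13. Over the genes called lower the median change was -0.587, with a median Cy5 change of -0.24 and a median Cy3 change of 0.281. A part of these falls thus lies in the reference. In all, 59 of 21242 genes passed, 45 higher and 14 lower, and over all genes tested the groups did not overlap in 3.88%, where chance gives 2.86%. The count was 28 at a 1.5-fold threshold, 29 with only the arrays of the groups compared, 248 with array weights, 232 without SECY 1 and 96 without SECY 3, and median centring in place of loess gave 41 higher and 30 lower. The majority of rises turned under some alternatives, among them array weights, where 111 genes were higher and 137 lower, and the fit without SECY 1, where 54 were higher and the rest lower. Untreated and SECY were scanned on the same day but lie on different slides, so no block separates the slide set from the diet.

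**Figure D1:**
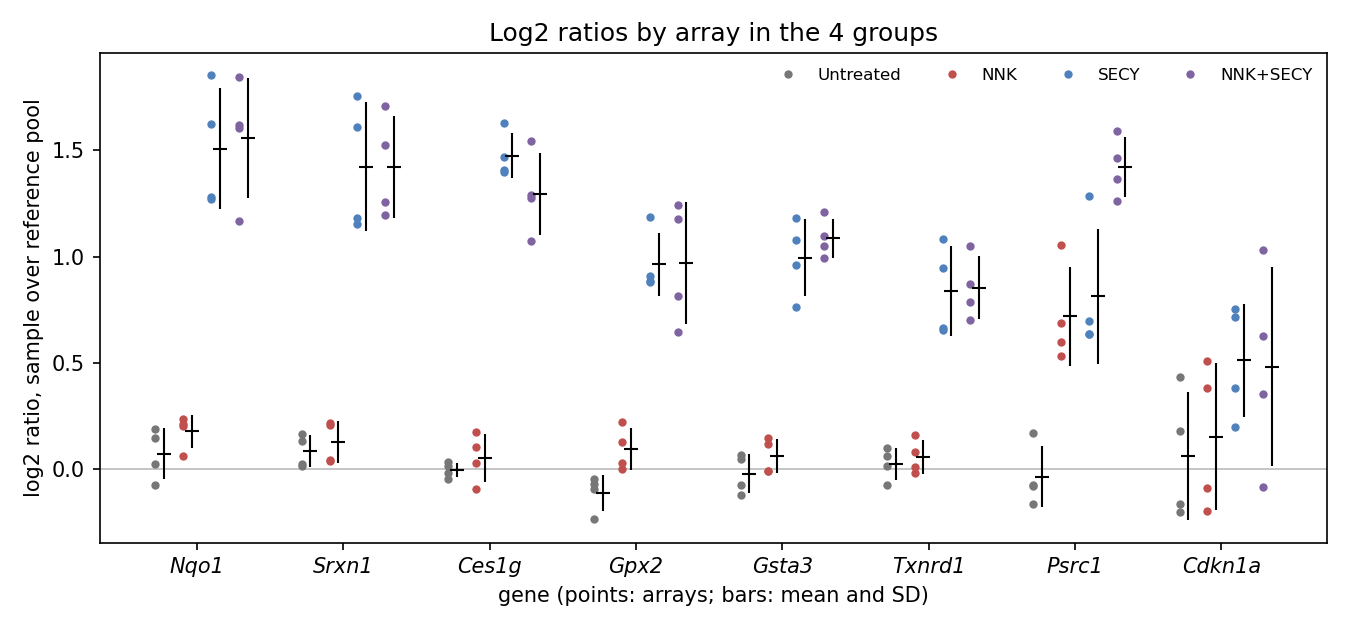
Log2 ratio of each array (points) for 8 genes in the 4 groups, on a y axis of sample over reference pool in log2, with the mean and SD of 4 arrays as bars. For Nqo1, Srxn1, Ces1g, Gpx2, Gsta3 and Txnrd1 the SECY and NNK+SECY arrays all lie above the Untreated and NNK arrays, while Psrc1 is also higher in NNK, by 0.76, than in Untreated.

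The NNK comparison asked what differed 13 days after the injection. The 68 genes that passed were all higher in NNK than in Untreated, with a median log2 fold change of 0.59. Upk3a, a uroplakin, rose by 0.74 ± 0.10, and Psrc1 rose by 0.76 (SE 0.14), while its other probes gave 0.11 to 0.34. Larger rises included those of Mcm8 and Rfc4, factors of DNA replication and repair, at 1.13 and 0.95 ± 0.14, and of the kinase Pak6 at 0.82 ± 0.09. Another probe of Mcm8 gave 0.042. The Cy3 signal, which is the same pool on every array, also rose at these genes, by a median of 1.24 beside 1.83 in Cy5. In 62 of the 68 genes, Mcm8, Rfc4 and Pak6 among them, the Cy3 means of some groups differed by more than 0.5, against 7.49% of all genes tested. In the other 6 the Cy3 changes from Untreated to NNK ranged from -0.105 to 0.379, with -0.012, 0.091 and 0.061 for Upk3a, Psrc1 and Krt15. Among the 19656 genes with a smaller Cy3 difference, a restriction chosen after the data were seen, these 6 keep their fold changes by construction. Upk3a passed there and the other 5 did not, with an adjusted p = 0.345 for Psrc1. Of these 19656 genes 762 had an unadjusted p below 0.05, a smaller share than the 0.05 that chance gives.

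Of 31 p53 targets 1 passed after NNK, Psrc1, which also passed when adjusted over the list alone, and 25 were above 0 (median 0.082, adjusted p = 0.000737, estimated 0.193). Psrc1 passed under 26 of its 33 alternatives. Ciliated cell markers were higher as a list (0 of 22 passed, and 2 when adjusted over the list alone; median 0.12, adjusted p = 0.000488, estimated 0.702). Of 34 proliferation genes 1 passed, Birc5, at 0.97 ± 0.13 (median 0.063, adjusted p = 0.0373, estimated 0.916), and of 26 T and NK cell markers 1 passed, Cd3e, at 0.44 ± 0.08 (median 0.066, adjusted p = 0.0305, estimated 0.825). Each was also the sole member past the threshold when adjusted over the list alone, and the reference signal of both differed by more than 0.5 between groups. Another probe of Cd3e gave 0.027, and Cd3e passed under 21 of its 33 alternatives. B and plasma cell markers (median 0.093, adjusted p = 0.0445, estimated 0.853) and mesothelial markers (median 0.063, adjusted p = 0.0373, estimated 0.825) were higher as lists with 0 members past the threshold. Of 31 alternatives, mesothelial markers passed under 18, proliferation genes under 20 and B and plasma cell markers under 22. Lower as lists, again with 0 members past it, were heat shock genes (median -0.11, adjusted p = 0.000488, estimated 0.825), alveolar macrophage markers (median -0.11, adjusted p = 0.000488, estimated 0.331), alveolar type 1 cell markers (median -0.09, adjusted p = 0.0082, estimated 0.321) and adipose tissue markers (median -0.15, adjusted p = 0.0315, estimated 0.825). The lung cytochrome P450 genes Cyp2a5 and Cyp2f2, at -0.53 ± 0.36 and -0.15 ± 0.08, and the DNA methyl repair gene Mgmt, at 0.07 ± 0.06, did not pass.

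Over all genes tested the groups did not overlap in 3.75%, where chance gives 2.86%. With the slide as a block 43 genes passed, and the median difference over the 68 genes within slides 1 to 4 ranged from 0.39 to 0.67. The count was 28 with the processed signals, 22 with the authors' deposited value table, 41 with median centring, 42 with only the arrays compared, 34 at a 1.5-fold threshold, 29 without Untreated 1, 35 without Untreated 2, 19 without Untreated 3, 132 without NNK 1, 21 without NNK 2, 18 without NNK 3 and 23 without NNK 4. The scan day follows NNK on all slides and cannot be told apart from it.

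**Figure D2:**
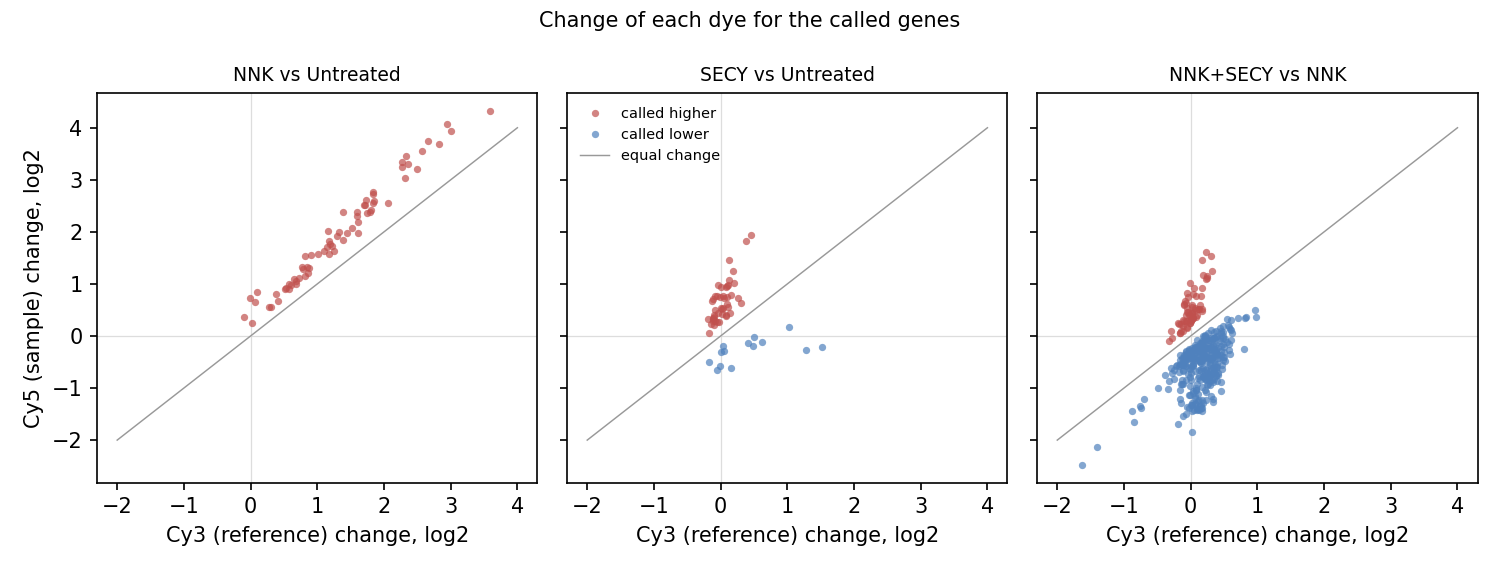
Change of the Cy5 signal (y axis, log2) against that of the Cy3 reference signal (x axis, log2) for each gene called higher or lower in 3 comparisons, with a line where both change equally. The genes called in NNK vs Untreated have a median Cy3 change of 1.24, while those called higher in SECY vs Untreated have a median Cy3 change of 0.02. Those called lower in SECY vs Untreated have a median Cy3 change of 0.28.

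Against Untreated, the mice given both treatments had rises of the enzymes that rose with the diet and of p53 targets. Nqo1 rose by 1.49 (SE 0.13), Srxn1 by 1.34 ± 0.13, Gsta3 by 1.11 ± 0.08, Gpx2 by 1.08 ± 0.11 and Txnrd1 by 0.83 ± 0.09. Psrc1 rose by 1.46 (SE 0.14), Ddit4l by 0.61 ± 0.07 and Zmat3, an RNA-binding p53 target, by 0.42 ± 0.08, so that 7 of 31 p53 targets rose, 0 fell and 24 did not pass, and 14 rose when adjusted over the list alone (median 0.18, adjusted p = 5.93e-16, estimated 0.000177). Other probes of Psrc1 gave 0.15 to 0.545, and those of Srxn1 0.39 to 0.52. Of the 36 NRF2 targets and glutathione enzymes 21 rose, 0 fell and 15 did not pass, and 28 rose when adjusted over the list alone (median 0.40, adjusted p = 8.5e-46, estimated 1.41e-06). Upk3a rose by 0.94 ± 0.10 and the basal cell keratin Krt15 by 0.89 (SE 0.12).

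Of 32 xenobiotic phase I enzymes 3 rose, Ces1g, Aldh1a1 and Aldh1a7, with 7 when adjusted over the list alone (median 0.12, adjusted p = 2.27e-06, estimated 0.09). Selenoproteins again had 2 called members, Gpx2 and Txnrd1, in a list whose median of -0.004 and mean of 0.091 differ in sign (adjusted p = 0.173). The desaturase Scd1 was the sole called member of 27 genes of fatty acid synthesis and oxidation, at 0.82 ± 0.16, and passed under 27 of its 34 alternatives. Ciliated cell markers (median 0.16, adjusted p = 2.27e-06, estimated 0.249), skeletal muscle markers (median 0.32, adjusted p = 0.018, estimated 0.685) and DNA repair genes (median 0.017, adjusted p = 0.0282, estimated 0.249) were higher as lists with 0 members called, of which skeletal muscle markers passed under 21 and DNA repair genes under 23 of 31 alternatives. Extracellular matrix genes were lower as a list, with Col14a1 called under 23 of its 34 alternatives and 2 that fell when adjusted over the list alone (median -0.14, adjusted p = 0.00114, estimated 0.514), and so were fibroblast and smooth muscle markers, with Mfap4 called under 17 of its 33 alternatives and 3 that fell when adjusted over the list alone (median -0.091, adjusted p = 0.0148, estimated 0.371). With 0 members called, antigen presentation class II (median -0.12, adjusted p = 0.00114, estimated 0.285), alveolar macrophage (median -0.11, adjusted p = 0.0026, estimated 0.249), cardiac muscle (median -0.15, adjusted p = 0.00521, estimated 0.612) and alveolar type 2 cell markers (median -0.11, adjusted p = 0.0111, estimated 0.249) and heat shock genes (median -0.12, adjusted p = 0.0346, estimated 0.763) were lower as lists.

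In total 339 genes passed, 114 higher and 225 lower, and over all genes tested the groups did not overlap in 6.78%, where chance gives 2.86%. Large falls included those of Lgr4, a receptor of Wnt signalling, at -1.43 ± 0.24 and Itgb8, an integrin subunit, at -1.24 ± 0.23. Over the alternatives Lgr4 ranged from -2.602 to -0.481 and Itgb8 from -2.207 to -0.603. Other probes of Lgr4 gave -0.008 and -0.003, and another probe of Itgb8 gave 0.04. The count of genes past the threshold was 199 without Untreated 1, 168 without Untreated 3, 200 without NNK+SECY 1, 164 without NNK+SECY 4, 527 with array weights, 156 at a 1.5-fold threshold and 134 among the brighter genes, a restriction chosen after the data were seen. Both the slide set and the scan day differ between these groups.

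The comparison of NNK+SECY with NNK asked what the diet changed in injected mice. Enzymes that rose without NNK also rose here, with no array shared between both comparisons. Nqo1 rose by 1.38 ± 0.13, Srxn1 by 1.29 ± 0.13, Gsta3 by 1.02 ± 0.08, Gstm1 by 1.00 (SE 0.09), Gpx2 by 0.87 ± 0.11 and Txnrd1 by 0.79 ± 0.09, and other probes of Srxn1 gave 0.43 to 0.56. Of the 36 NRF2 targets and glutathione enzymes 19 rose, 0 fell and 17 did not pass, and 29 rose when adjusted over the list alone (median 0.37, adjusted p = 4.65e-47, estimated 1.21e-06). Of 31 p53 targets 3 rose, 0 fell and 28 did not pass, with 5 when adjusted over the list alone (median 0.14, adjusted p = 4.32e-08, estimated 0.00484), namely Psrc1 at 0.70 ± 0.14, Ddit4l at 0.39 ± 0.07 and Gdf15 at 0.33 ± 0.07. Other probes of Psrc1 gave 0.045 to 0.20. Of 32 xenobiotic phase I enzymes 2 rose, with 8 when adjusted over the list alone (median 0.15, adjusted p = 2.34e-08, estimated 0.0315).

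Antigen presentation class II was lower as a list, with all 15 members below 0, 0 called and 1 that fell when adjusted over the list alone (median -0.24, adjusted p = 1.1e-06, estimated 0.141), and so were mesothelial markers, with 9 of 9 members below 0, 0 called and 4 that fell when adjusted over the list alone (median -0.19, adjusted p = 0.0012, estimated 0.283). Of 8 mast cell markers the protease Cma1 fell, at -0.31 ± 0.05 (another probe -0.073), with 1 that rose and 2 that fell when adjusted over the list alone (median -0.094, adjusted p = 0.0274, estimated 0.273). Mfap4 fell among 20 fibroblast and smooth muscle markers, of which 1 rose and 3 fell when adjusted over the list alone (median -0.093, adjusted p = 0.019, estimated 0.439) and Cd3e among 26 T and NK cell markers (median -0.058, adjusted p = 0.0274, estimated 0.776). For Cd3e, at -0.36 ± 0.08, the Cy5 change was -0.078 and the Cy3 change 0.277, so most of its fall is a rise of the reference. Another probe gave 0.05, and Cd3e passed under 26 of its 33 alternatives. Extracellular matrix genes (median -0.14, adjusted p = 0.0305, estimated 0.776) and cardiac muscle markers (median -0.15, adjusted p = 0.0362, estimated 0.776) were lower as lists with 0 members called. Skeletal muscle markers (median 0.39, adjusted p = 0.00133, estimated 0.776) and immediate early genes (median 0.073, adjusted p = 0.0274, estimated 0.335) were higher as lists with 0 members called, and fatty acid synthesis and oxidation with Scd1 called at 0.84 ± 0.16 (median 0.083, adjusted p = 0.0373, estimated 0.776). Of 31 alternatives, the list of fatty acid synthesis and oxidation passed under 20 and mast cell markers under 24. Spry4, a feedback inhibitor of RAS-MAPK signalling, rose by 0.43 ± 0.10 in a list that did not pass (adjusted p = 0.327), and it passed under 25 of its 34 alternatives, with a Cy5 change of 0.25 and a Cy3 change of -0.18.

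In total 371 genes passed, 65 higher and 306 lower, and over all genes tested the groups did not overlap in 8.36%, where chance gives 2.86%. The genes called lower had a median log2 fold change of -0.63, made of a Cy5 change of -0.47 and a Cy3 change of 0.17. They included Dnajb8, Acot6 and Lgr4 at -1.60 ± 0.24, -1.60 ± 0.24 and -1.55 ± 0.24. These sizes depend on the processing. Over the alternatives Dnajb8 ranged from -3.087 to -1.527, Acot6 from -3.082 to -0.893 and Lgr4 from -2.772 to -0.499. Other probes of Acot6 gave -1.07 and -0.01, and those of Lgr4 -0.015 and 0.064. In 80 of the genes called lower other probes of the gene were above the filter, and their mean change was a median of 0.041 of that of the chosen probe. The corresponding median was 0.658 over 24 of the genes called higher, which were brighter, with a median log2 intensity of 8.5 against 7.21. The count stayed within a factor of 1.5 of 371 under all alternatives except the 1.5-fold threshold, at 189, and the brighter genes, at 172, of which the latter was chosen after the data were seen. NNK and NNK+SECY were scanned on the same day and lie on different slides, so the slide set and the diet cannot be told apart.

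**Figure D3:**
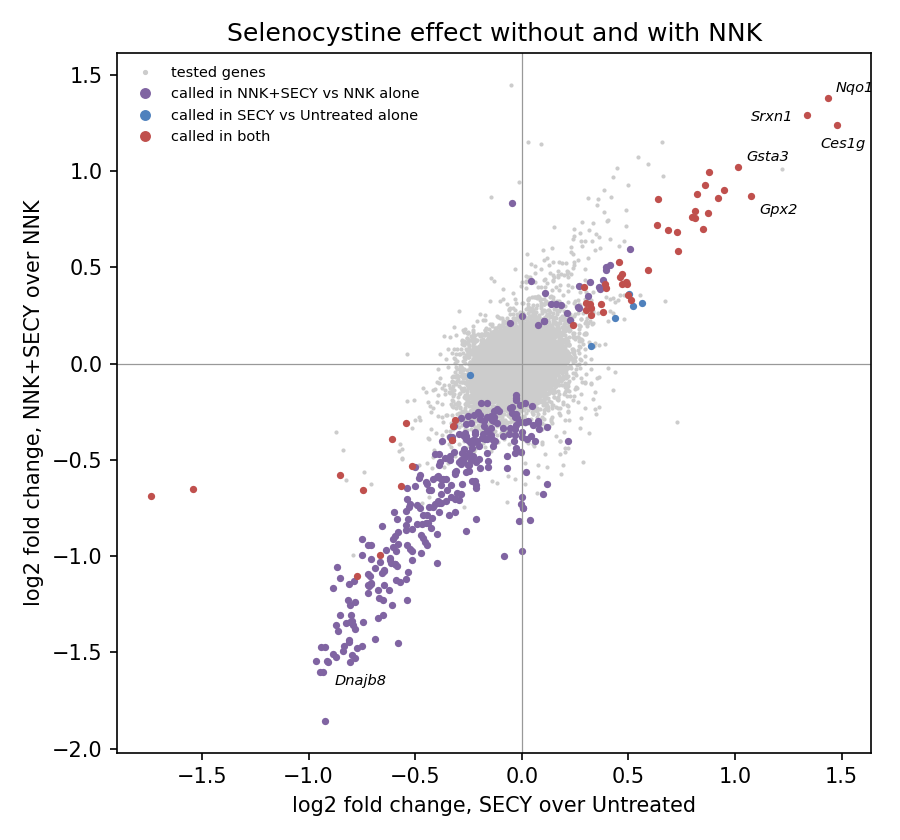
Log2 fold change of NNK+SECY over NNK (y axis) against that of SECY over Untreated (x axis) for every gene tested, with called genes in colour. Of the genes called higher in SECY, 40 were also called higher on the y axis, and the correlation over all genes was 0.576.

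Under selenocystine, NNK left few calls. Upk3a was higher in NNK+SECY than in SECY, by 0.72 ± 0.10 (limma adjusted p = 0.0341), and passed under 10 of its 32 alternatives. A transcript named only by its cDNA clone was the other of the 2 genes that passed, and 1304 genes had an unadjusted p below 0.05. Over these 2 genes the median Cy5 change was 0.38 and the median Cy3 change -0.291. Krt15 at 0.63 (SE 0.12), Scd1 at 0.87 ± 0.17, the platelet receptor P2ry12 at 0.35 ± 0.07 and Cavin2 at 0.59 ± 0.10 were among the next by p and did not pass. Heat shock genes were lower as a list with all 19 members below 0 and 0 called (median -0.20, adjusted p = 2.17e-06, estimated 0.804), as was antigen presentation class II (median -0.12, adjusted p = 0.00302, estimated 0.804). Ciliated cell markers (median 0.10, adjusted p = 0.00267, estimated 0.804), skeletal muscle markers (median 0.32, adjusted p = 0.00268, estimated 0.804), p53 targets (median 0.063, adjusted p = 0.0096, estimated 0.62) and cholesterol synthesis genes (median 0.082, adjusted p = 0.0376, estimated 0.804) were higher as lists with 0 members called, of which the last passed under 23 of 31 alternatives. The count was 0 with the slide as a block, 7 without SECY 2, 1 without NNK 1 or Untreated 1, and 0 without any other array.

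The interaction asked whether the NNK effect differed with and without selenocystine. The same clone-named transcript was the 1 gene that passed, with 979 at an unadjusted p below 0.05 and 0 with the slide as a block. The count was 3 without NNK+SECY 4, 1 without NNK 1, SECY 2 or Untreated 3, and 0 without any other array. Txnrd1, Mgmt and Cdkn1a had interaction terms of -0.02 ± 0.13, -0.12 ± 0.09 and -0.12 ± 0.31 and did not pass. Antigen presentation class II (adjusted p = 0.000535) and proliferation genes (adjusted p = 0.00343) were lower as lists, and skeletal muscle markers (adjusted p = 0.0024) and alveolar macrophage markers (adjusted p = 0.0215) were higher, with 0 members called in each. Their medians were -0.17, -0.079, 0.41 and 0.13, and all 4 had an adjusted p = 0.982 with an estimated correlation. Of 30 alternatives, alveolar macrophage markers passed under 19 and proliferation genes under 24.

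Across genes, which are not independent replicates, the selenocystine effects without and with NNK correlated with Pearson r = 0.576 and Spearman rho = 0.271 over 21237 genes, and the NNK effects without and with selenocystine with r = 0.131 and rho = 0.071. These effects share no array. Of the 45 genes called higher in SECY, 40 were among the 65 called higher in NNK+SECY vs NNK, where independent lists would share 0.138, and of the 14 called lower 13 were among the 306 called lower, where independent lists would share 0.202. The reference differed by more than 0.5 between groups in 1 of these 40 genes and in 5 of these 13, and the slide set differs in both comparisons. The comparisons with Untreated share its arrays. There, SECY and NNK+SECY shared 42 genes called higher, where independent lists would share 0.242, simulated unchanged groups shared 0, and the untreated arrays split 2 and 2 gave 16 to 20. The simulated groups, here and in the next overlap, held independent noise with no change. Few genes can be called in them, so their 0 was nearly given in advance and does not measure what shared controls add. NNK and NNK+SECY shared 9 genes called higher, where independent lists would share 0.365, simulated unchanged groups shared 0, and split untreated arrays gave 0 to 1. In 5 of these 9 genes the Cy3 reference differed by more than 0.5 between groups and rose in NNK+SECY over Untreated by 0.896 to 2.292. In the other 4 it differed by at most 0.5 between groups. Their Cy3 changes in NNK+SECY over Untreated were 0.002 to 0.024, a range that does not cover NNK vs Untreated. Both comparisons also differ in scan day.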

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

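The tests of the 3 patterns weighed here were chosen after the values had been seen, while the splits of the samples were planned.

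The first pattern is the set of 68 genes higher in NNK than in Untreated. An effect of NNK on the RNA of the lungs alone would leave the reference pool in Cy3 where it was, but the median Cy3 change over these genes was 1.239 (quartiles 0.718 and 1.807) against -0.002 over all genes, which argues against NNK as the whole source. In the 4 slides taken singly the Cy3 change was 0.80, 1.38, 1.54 and 1.18, so no single slide carries it. A signal brought by the scan day may be the source, but between NNK+SECY and SECY, which were scanned on the same pair of days, the median Cy3 change of these genes was 0.336 (quartiles 0.072 and 0.448), so the scan day and another event on slides 1 to 4 cannot be told apart. In Upk3a, Psrc1 and Krt15 the Cy3 changes were -0.012, 0.091 and 0.061, so the reference moved little there. An effect of the scan day on Cy5 alone was not tested, so these genes are not cleared of it. Upk3a passed under 32 of its 32, Psrc1 under 26 of its 33 and Krt15 under 16 of its 34 alternatives. For Upk3a these are only the alternatives in which it was tested. Its intensity lay below the median of 7.33 over all genes, so the restriction to brighter genes left it out.

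The second pattern is the set of 306 genes lower in NNK+SECY than in NNK, among them Lgr4, Itgb8 and Dnajb8. In 80 genes the other probes changed by a median of 0.041 of the chosen probe's change (quartiles -0.024 and 0.146). In 24 genes called higher the median was 0.658. The other probes are dimmer than the chosen one, since the brightest was chosen. The genes called lower were also dimmer, with a median log2 intensity of 7.21 against 8.5. These shares are thus not matched for intensity, and a fall of all transcripts of each gene is left open. A rise of the Cy3 reference alone made up a median of 0.253 of the fall (quartiles 0.015 and 0.525) and stays open for some of the genes. SECY minus Untreated, also between the slide sets, had a median of -0.358 over these genes (quartiles -0.602 and -0.187) beside -0.633 for NNK+SECY minus NNK. Both the slide set and selenocystine predict this fall, and neither predicts that SECY 1, at a median of 0.006, lay apart from SECY 2 to 4 (-0.443 to -0.277) and from NNK+SECY 1 on the same slide (-0.441), so they cannot be told apart, and an effect of selenocystine on single transcripts of these genes may also remain.

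The third pattern is the rise of NRF2 targets and glutathione enzymes with selenocystine, such as Nqo1, Srxn1 and Txnrd1. A difference of the spots between the slide sets that acts on both dyes is argued against by the Cy3 signal, which changed by a median of 0.095 (quartiles -0.04 and 0.112) over the 17 called members against 0.81 for their log2 fold change. A higher share of club cells is argued against by 11 club cell markers that are not in the enzyme lists, with a median of 0.003 (quartiles -0.052 and 0.095). Other probes of 9 called members gave a median of 0.677 of the change. A response to selenocystine is a candidate explanation, and a difference in Cy5 labelling between the slide sets was not excluded.

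Other splits of the same arrays were tested for each count of genes. For NNK vs Untreated 1 of 35 splits, the real one with 68 genes, gave as many, and the highest other gave 1. As Untreated and NNK share slides, the splits that part every slide are the closer match, and these are 8, too few for a share below 0.05 (highest other 0). With the slide as a block 43 genes passed. For NNK+SECY vs Untreated (339 genes, 1 of 35, highest other 1) and NNK+SECY vs NNK (371 genes, 1 of 35, highest other 1), whose groups share no slide, the share is below 0.05. This argues against chance as the source of the counts. As 1 of 35 is the lowest share these splits can reach, chance is not excluded. For SECY vs Untreated 2 of 35 splits gave at least the real 59 genes, so chance is not excluded by this count. The other split exchanged SECY 3 and Untreated 1 and called 1164 genes, 661 higher and 503 lower, of which 1 was also called in the real split, which points to a structure of the samples beside the diet. An exchange of labels is not borne out by Nqo1, whose log2 ratio was 1.27 on SECY 3 and 0.15 on Untreated 1. For NNK+SECY vs SECY 2 of 35 splits gave at least the real 2 genes, with 3 as the highest other, in a split that kept 2 slides whole, and with the slide as a block 0 genes passed in limma while 1304 had an unadjusted p below 0.05 without the block. Of the 8 splits that part every slide, 1, the real one, gave as many (highest other 0), and 8 are too few for a share below 0.05. For the interaction 7 of 100 splits gave at least the real 1 gene, with 159 as the highest other. These splits moved arrays freely between groups and slides, so the changes with the diet enter them. Chance is not excluded for NNK+SECY vs SECY or for the interaction.

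The NNK effect with and without selenocystine differed by the interaction test in 1 transcript, named only by its cDNA clone, with an interaction term of 0.89, and in 4 lists. These were antigen presentation class II (adjusted p = 0.000535, median -0.17) and proliferation (adjusted p = 0.00343, median -0.079), with lower terms, and skeletal muscle (adjusted p = 0.0024, median 0.41) and alveolar macrophage markers (adjusted p = 0.0215, median 0.13), with higher terms. None of the 4 passed with an estimated correlation.

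In data outside the comparisons, the spots of the E1A a107 control, which measures RNA added to the samples, had a median Cy3 signal of 409.2 on the arrays of slides 5 to 8 and 60.6 on those of slides 1 to 4, and a median Cy5 signal of 551 and 64.6. The eQC control spots had 1096 and 393 in Cy3. No biological explanation was tested, since these spots do not measure lung RNA. The slide sets thus differ in both dyes apart from the lung RNA, which bears on the genes lower in NNK+SECY, where the slide set was left open. For the NRF2 targets a difference in both dyes was argued against by their own Cy3 signal.

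Some samples lay apart from the other 3 of their group by Dixon's test, in 57 of 736 values by gene and group, or 7.74%, where chance gives about 1 in 20. The test weighs a gap against the range of the 4 values, so some of the gaps are small. Zfp740 on NNK+SECY 2, for example, was at 0.252 against 0.269 to 0.271 on the other arrays. Values are log2 ratios. On Untreated 1 these were Ccnb2 at 0.23, Cyp2a5 at -1.04, Dio2 at 0.19, Per2 at -0.79, Sftpa1 at 0.023, Stard4 at -0.054 and Tk1 at 0.16. On Untreated 2 they were Tnnc2 at 0.757 and Tnni2 at 0.565, both of skeletal muscle, and on Untreated 4 Dgkq at 0.225. NNK 1 had Batf3 at 0.16, Myod1 at 0.60 and Pak6 at 0.69. NNK 2 had Cbr2 at -0.12, Cd74 at 0.097, Kit at -0.14, Mamdc2 at 0.19 and Sox17 at 0.115. NNK 3 had Ky at 0.46 and Selenoo at 0.22, and NNK 4 had Acadvl at -0.365, Lss at 0.20 and Marco at -0.58.

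On SECY 1 the values were Cd247 at -0.092, Itgb8 at 0.11, Ppara at -0.044, St6galnac5 at 0.002 and Xpc at 0.056. On SECY 2 they were Cldn15 at 0.32, Dgkq at 0.035, Gpx2 at 1.19 and Psrc1 at 1.29. SECY 3 had Krt14 at 0.22, Pcna at -0.17, Scgb3a1 at -0.64, Selenos at -0.31 and Tnnc2 at 0.24, and SECY 4 had Batf3 at -0.11 and Cd4 at -0.13. NNK+SECY 1 had Cma1 at -0.135, Cnn1 at -0.057, Gsx1 at 0.17, Mcm8 at 0.074 and Myh6 at 0.25. NNK+SECY 2 had Adamts4 at -0.59, Dnajb8 at -0.535, Mgmt at -0.023 and Zfp740 at 0.25. NNK+SECY 3 had Igfbp3 at -0.55, Mamdc2 at -0.17, Ppara at 0.59, Prox1 at 0.335, Selenop at 0.76 and Sephs2 at 0.63. NNK+SECY 4 had Batf3 at -0.17, Fcer1a at -0.25 and Gpx4 at -0.09.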

How the results depend on the processing

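The restrictions to genes with a stable reference signal and to brighter genes were chosen after seeing the data, and the other alternatives were planned. The cause of a move was not tested, except that a 1.5-fold threshold, fewer genes and fewer arrays change a count by construction. For the named genes, 1801 of 1899 called values under the alternatives stayed past the threshold and 98 did not, with 0 reversed. For the list tests 742 of 806 stayed, 63 did not, and the mast cell markers in NNK+SECY vs NNK turned direction among the brighter genes (adjusted p = 0.647, where its 31 alternatives ranged from 0.0159 to 0.647). Without 1 array, 1592 of 1744 called gene values and 753 of 864 list values stayed.

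The count of 68 in NNK vs Untreated became 28 with the processed signals, 41 with median centring, 22 with the deposited value table, 42 with only the arrays compared, 43 with the slide as a block, 34 at 1.5-fold and 1 with a stable reference signal, and 18 (without NNK 3) to 132 (without NNK 1) without 1 array. The count of 59 in SECY vs Untreated became 29 with only the arrays compared, 248 with array weights (111 higher and 137 lower), 110 with the replicate block (51 and 59) and 28 at 1.5-fold, 42 higher and 23 lower with an offset of 10 and 41 and 30 with median centring, and 44 (without Untreated 4) to 232 (without SECY 1, 54 of them higher) without 1 array, so array weights, the replicate block and leaving out SECY 1 each turned the majority from higher to lower. The count of 339 in NNK+SECY vs Untreated became 527 with array weights, 156 at 1.5-fold and 134 among the brighter genes, 83 higher and 294 lower with median centring, and 164 (without NNK+SECY 4) to 428 (without SECY 3) without 1 array. The count of 371 in NNK+SECY vs NNK became 189 at 1.5-fold and 172 among the brighter genes, and 279 to 496 without 1 array.

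The count of 2 in NNK+SECY vs SECY became 1 with a filter on both dyes and 0 with an offset of 10, the processed signals, the value table, the mean of probes, only the arrays compared, trend and robust moderation, the slide as a block, a stable reference signal and the brighter genes, and ranged from 0 to 7 (without SECY 2) without 1 array. In limma 1304 genes had an unadjusted p below 0.05 there. The count of 1 in the interaction became 2 with the replicate block. It became 0 with no background correction, an offset of 10, the processed signals, median centring, the value table and no filter. It was also 0 with the mean of probes, trend and robust moderation, the slide as a block, a stable reference signal and the brighter genes. Without 1 array it was 0 to 3 (without NNK+SECY 4). In limma 979 genes had an unadjusted p below 0.05 there, a smaller share than the 0.05 that chance gives. The count of 42 genes shared by SECY and NNK+SECY against Untreated became 20 with only the arrays compared, 71 with array weights and 20 at 1.5-fold. The correlations of effects moved by less than their jackknife SE of 0.184 (selenocystine) and 0.2 (NNK), and the 54 list results past the threshold stayed within 1.5 times.

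The numbers in the sample names were checked as pairs with a paired replicate block. The labels do not say that a number marks a batch, and not every pair of arrays with the same number correlated, so they were not used to pair the samples. The 4 correlations were 0.464, 0.18, 0.366 and -0.013 for Untreated and NNK, where the number is also the slide (mean of other pairs -0.083), and 0.504, 0.185, 0.5 and -0.1 for Untreated and SECY (other pairs -0.1). In the other 4 pairs of groups they ranged from -0.122 to 0.323. Of 8 arrays 6 correlated best with their own number for Untreated and NNK and 5 for Untreated and SECY, a hint that some numbers share more than a name. The scan day as a block was not run, since each group was scanned on 1 day and it adds nothing to the group means. The slide could enter the model as fixed only for NNK vs Untreated, NNK+SECY vs SECY and the interaction, and as random for the other comparisons, with a correlation of 0.12 between the arrays of a slide. The interaction and the correlations were not run on only the arrays compared, the correlations not under another moderation or threshold, and the list tests not under the slide block, moderation or threshold. Signal over background limits the dim genes: 66.3% to 79.3% of spots were well above background in Cy5.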

Other observations

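The test of whether the changes of the p53 targets add up was chosen after the list results had been seen, and the gene and list tests were planned.

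Gene lists that passed in no comparison had these lowest adjusted p over the 6 comparisons: circadian clock 0.562, club cells 0.0875, endothelial cells 0.0615, ER stress and amino acid response 0.198, erythroid cells 0.0615, glucocorticoid response and metallothioneins 0.0906, inflammatory cytokines and acute phase 0.221, mitochondrial respiratory chain 0.282, neutrophils and granulocytes 0.0949, platelets and megakaryocytes 0.152, RAS-MAPK output 0.316, selenoproteins 0.0799, thymus and immature T cells 0.166, tracheal and esophageal epithelium 0.0562 and type I interferon response 0.119. Single members passed in some of them. Krt15 rose in NNK among 8 markers of tracheal and esophageal epithelium (list adjusted p = 0.163), under 16 of its 34 alternatives. Bpifa1 fell in NNK+SECY against Untreated, by 0.42 on the log2 scale, among 14 club cell markers of which 2 rose, Aldh1a1 and Retnla, the latter by 1.16 (SE 0.23) and under 21 of its 34 alternatives. The fall of Bpifa1 passed under 10 of its 34 alternatives. Sox17 fell among 18 endothelial markers in NNK+SECY against Untreated and against NNK, at -0.40 and -0.47, while its other probes ranged from -0.32 to -0.038 against Untreated and from -0.44 to 0.041 against NNK, and it passed under 23 of its 34 alternatives against Untreated and under 33 against NNK.

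The transcripts of the clock genes Arntl, Dbp and Per2 did not pass in any comparison. In NNK+SECY vs NNK they were at 0.33 (SE 0.19), -0.75 (SE 0.43) and -0.26 ± 0.30.

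The p53 targets had a median change of 0.11 after selenocystine, of 0.18 with both treatments and of 0.082 after NNK. The NNK rise passed only at the preset correlation and not with an estimated one (adjusted p = 0.193), and 1 of the 31 genes passed in it. One hypothesis was that both changes add up on the log2 scale. The median departure from the sum over the 31 genes was 0.005 (quartiles -0.096 and 0.057), within a bound of 0.1, but the NNK change alone is below that bound, so the test could hardly have come out otherwise and additivity may or may not hold.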
